A study of Mus musculus with 6 samples.

How the data were processed

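Whole kidneys of wild-type mouse embryos at embryonic day 18.5 were profiled by droplet-based single-cell RNA sequencing, per the labels. In this assay (Chromium, 10x Genomics) each cell is caught in a droplet and its transcripts are tagged near their 3′ end with a barcode of the droplet and a unique molecular identifier (UMI), so that a UMI stands for 1 captured transcript. The series holds 6 samples, all in 1 group, called libraries 1 to 6 here. For library 6 the code in the sample title and that of the deposited files differ, and the files were used as the record assigns them. Without library 6 the 4 comparisons gave 4966, 1391, 6145 and 9283 genes. The labels do not state that the libraries came from separate animals. Sex genes, given at the end, show that not all came from the same animal, but not how many animals there were. The p-values measure only the spread between these samples, which may be in part technical. As there is 1 group, no comparison between groups of samples was possible, and the comparisons below set cell classes against each other within the same libraries.

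The deposited files hold counts: whole numbers of UMIs per gene and barcode, without normalization, for every barcode, empty droplets included. The submitters' processing notes name Cell Ranger 6.1.2 and the genome build mm10 (GRCm38). The matrices record other software versions, per the file headers: Cell Ranger version 4 in libraries 1 to 3 and version 3.1.0 in libraries 4 to 6. The gene annotation, and whether reads from introns were counted, are not given in the sources used here. The deposited counts list 32285 genes in libraries 1 and 2, 28693 in library 3 and 28692 in libraries 4 to 6. These differences form the technical batches used below. The 27734 identifiers present in every library were used, which held 99.3% to 99.7% of the UMIs of each library. Among them 1228 carried different symbols in the gene lists, and 32 symbols occurred more than once, so genes were matched by Ensembl identifier. The one extra entry of library 3 was EYFP, a fluorescent reporter. Coordinates come from the GENCODE M21 annotation of GRCm38, counted from 1, and give the whole gene. For reads counted per gene no exon, intron or untranslated region can be assigned to a value. Whether counting used the strand is not given in the sources used here.

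Library totals were 154816873, 137812806, 134657578, 132617963, 116539933 and 99788124 UMIs in libraries 1 to 6. A barcode was called a cell when it had at least 10% of the UMIs found at the 99th percentile of the 3000 largest barcodes of its library, at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. The first condition set cutoffs of 13390, 16207, 13320, 14287, 16016 and 12431 UMIs and left 2919, 2172, 2914, 2290, 1962 and 1765 barcodes. All conditions together left 2769, 2118, 2688, 2183, 1676 and 1611 cells. No more than 4 called barcodes were shared by any pair of libraries. Doublets were marked per library by Scrublet in scanpy. Its automatic threshold marked under 0.5% of the cells in libraries 1, 2 and 6, where the 5% of cells with the highest scores were removed instead. In all, 146, 116, 60, 14, 17 and 84 cells were removed, which left 12608 cells.

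No cell annotation was used here, so cell classes were rebuilt. The UMIs of each cell were split at random into equal parts (binomial thinning with probability 0.5). One part served for clustering and naming, and the other for every level and test. Clustering used 2000 variable genes without the genes of the lists described below, 30 principal components, 15 neighbours and Leiden clustering at resolution 1, separately in each library. It gave 135 clusters. A cluster was named after the class of which the largest share of markers was detected in at least 20% of its cells and raised by a log2 fold change of at least 1, with at least 3 such markers. It stayed unnamed where another class had more markers among the top 10 genes by fold change, or where its median UMI count was low with none of its own markers among them. A pair of further rules was set after the first clustering had been seen. A gene found in about the same share of cells in every cluster (within 1.5 times) was left out of naming, and a cluster with 3 markers of a second class and one of them among its top genes stayed unnamed. Unnamed cells made up 28.0%, 29.0%, 20.4%, 7.70%, 12.4% and 8.38% of libraries 1 to 6, and those unnamed by the rule on a second class 0%, 16.7%, 5.52%, 2.81%, 0% and 4.85%. Those unnamed because another class led the top genes made up 24.5%, 11.1%, 7.88%, 0.738%, 8.44% and 2.69%. The names mean that a cluster was like the named type by its markers, so "stroma" below stands for interstitial stroma-like cells and "distal nephron" for distal nephron-like cells, and likewise for the other classes. Because other UMIs of the same cells built the classes, genes that separate cell types are by construction among those that differ. The genes of the lists had no part in the clustering. The markers that named the classes belong to the same cell types, however, so a list of a type's own genes is not independent of the naming.

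For each comparison the UMIs of the test part were summed per library and class, over libraries with at least 20 cells of both classes. Cells were never treated as replicates. The sums were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with the library as a block, TMM normalization and edgeR's default filter on low counts. All adjusted p-values of single genes below come from this test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The library is a block because both classes of a library come from the same sample. Standard errors (SE) were taken from the F statistic. Levels are given as CPM, as mean ± SD over libraries. Beside a fold change, CPM are per effective library size, the UMIs of the tested genes times the TMM factor, so the same class has slightly different values in different comparisons. Counts of libraries in which a gene was higher or lower use the same scale, unless stated. For genes that were not tested, single libraries, sums of markers, the plot of injury genes and the closing section, CPM are per total UMIs of the class in a library. Fold changes are on the log2 scale as fitted by edgeR, and a value given for a gene as an example of a list is its log2 fold change ± SE. Where a class had 0 UMIs of a gene, the fold is a lower bound against a floor of 3 UMIs over the libraries, and with 1 to 3 UMIs a ratio with an exact 95% counting interval is given. Intervals and floors cover counting error only. Shares of cells have exact (Clopper-Pearson) 95% intervals.

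The test was tested on simulated data, with counts drawn from the mean of each gene, the library sizes and the common dispersion of the real sums, random library effects, and 200 genes changed. For stroma against nephron progenitors (10975 genes) 96.0% of the genes changed 2-fold were recovered, for mural cells against stroma (9344 genes) 75.5%, for distal nephron against proximal tubule (11955 genes) 91.0%, and for proximal tubule against nephron progenitors (11862 genes) 98.0%. In each of the 4 comparisons 100.0% of the genes changed 4-fold were recovered. False calls made up 4.39%, 2.25%, 2.58% and 3.45% of the calls, and 0 recovered genes had the wrong sign. The real comparisons called far more genes than were changed here, and all simulated genes had the same dispersion. These rates may therefore not hold for the real data.

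There were 21 gene lists. The lists, the markers, the cell filters, the tests and the rule for named genes were fixed before the data were examined. The numbers of variable genes, components and neighbours and the thresholds for naming clusters were set later, before the first clustering. They are interstitial matrix, basement membrane, contractile, fibroblast activation, tubular injury, oxidative phosphorylation, fatty acid oxidation, glycolysis, proximal tubule transport, thick limb and distal tubule ion transport, epithelial junction and polarity, mesenchymal, cell cycle, hedgehog, Wnt, Notch, retinoid, FGF and receptor tyrosine kinase response, immediate early and dissociation stress, hypoxia, and interferon with MHC class I. A list with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The p-values were adjusted over all lists and comparisons. Camera compares a list with all other genes, and fry asks whether a list's genes move, on balance, one way. List p-values are camera's unless stated. Levels of markers of 17 cell types, including neural, adrenal cortex, mesothelium, liver and skeletal muscle cells that kidney dissections can hold, were summed in every compared class.

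The genes named were fixed by rule. In each comparison they are the 8 largest fold changes in each direction among called genes with the same sign in every library and a mean of at least 50 CPM in the higher class, leaving out the class markers, mitochondrial and ribosomal genes, gene models without a name and symbols carried by several identifiers. To these come the 2 members with the smallest p of each list called by camera. Acta2, Col1a1, Postn, Fap and Vim were always named with stroma, and Havcr1, Lcn2, Vcam1, Spp1, Krt20, Krt8, Clu and Sox9 with the proximal tubule, where tested. Some genes that the rule names are not reported here, among them 2 of those with a library far from the others. Of the 137 identifiers so named, 35 overlap another gene on the same strand and 55 on the opposite strand in the annotation, so their counts may hold reads of a neighbour. The Ugt2b, Cyp2j and Slc22a genes and the claudins belong to families of similar genes, and their counts are uncertain where reads fit several members.

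Alternatives were relative log expression factors, DESeq2, no low-count filter, no block, all UMIs of the same cells, another random split, doublets kept, clusters from markers alone, resolution 2, 1 joint clustering, at least 1000 genes per cell, at most 10% mitochondrial UMIs, leaving out each library, and each technical batch alone. For the class shares, every barcode with at least 1000 UMIs was a further alternative. Some alternatives were chosen after seeing the data. These are that last setting for the gene tests, the clustering, cell filter and random split settings for the lists and named genes, each technical batch for the named genes, and naming without the pair of later rules, which was the first naming tried. Software was Python 3.11.15 with scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.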

Results

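Whole kidneys of wild-type mouse embryos at embryonic day E18.5, a stage at which nephrons still form from progenitors while the first tubules already carry transporters, gave 6 libraries of single-cell transcriptomes in 1 group. The series concerns fibroblasts and the distal tubule. These libraries give wild-type levels for stroma and for a distal nephron class whose markers cover thick limb and distal tubule together. Called cells held a median of 20687, 27793.5, 22467, 24299, 28112.5 and 23329 UMIs and 5295, 6050, 4926.5, 5317, 5547 and 5212 detected genes in libraries 1 to 6. Their median mitochondrial share was 5.96%, 5.35%, 6.17%, 6.39%, 6.50% and 5.60%, and they held 51.8%, 58.7%, 62.0%, 59.0%, 56.9% and 52.2% of all UMIs of their library.

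The cells of the nephron lineage were the most frequent. Nephron progenitors made up 15.9% ± 3.44 of the cells (SD, n = 6), early nephron cells 14.6% ± 2.86, proximal tubule 13.1% ± 4.54, distal nephron 10.8% ± 3.63 and podocytes, the filter cells of the glomerulus, 2.88% ± 1.84. Ureteric epithelium, which forms the collecting ducts, made up 4.22% ± 0.876, and endothelial cells 6.62% ± 3.40. Interstitial stroma, the fibroblast lineage, made up 9.22% ± 6.79 by clusters so named, and this share differed between libraries by more than counting error. It was 5.99% (exact 95% interval 5.11% to 6.96%), 5.14% (4.22% to 6.21%), 11.7% (10.4% to 13.1%), 13.6% (12.0% to 15.4%) and 18.9% (16.9% to 20.9%) in libraries 1, 2, 4, 5 and 6. In library 3 no cluster was named stroma. The intervals cover the counting of cells only. Libraries 1 and 2, low in stroma, were counted on the longer gene list and had the most unnamed cells. Batch and naming therefore cannot be told apart from the tissue. With every barcode of at least 1000 UMIs stroma was 16.8%, the largest mean share of a named class. It was then 14.1%, 12.7%, 2.16%, 33.0%, 19.1% and 19.4% in libraries 1 to 6, so library 4 was highest in place of library 6. Mural cells, the contractile and renin-producing cells of the vessels, made up 3.43% ± 2.58. No cluster of library 2 was named mural, where 2.07% were mural with every barcode of at least 1000 UMIs. Smaller classes were intercalated cells with 0.851% ± 0.979, immune cells with 0.503% ± 0.348 and erythroid cells with 0.0888% ± 0.217. Of the clusters with markers of mesothelium, those of libraries 3 and 5 (20 and 7 cells) were led by genes of the urothelium, among them Upk3a and Krt5, and are not read as mesothelium, which leaves 7 cells of library 4. Unnamed cells made up 17.7% ± 9.56 and were most frequent in libraries 1 to 3 (28.0%, 29.0% and 20.4%), so a class without a named cluster has no upper limit there.

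**Figure D1:**
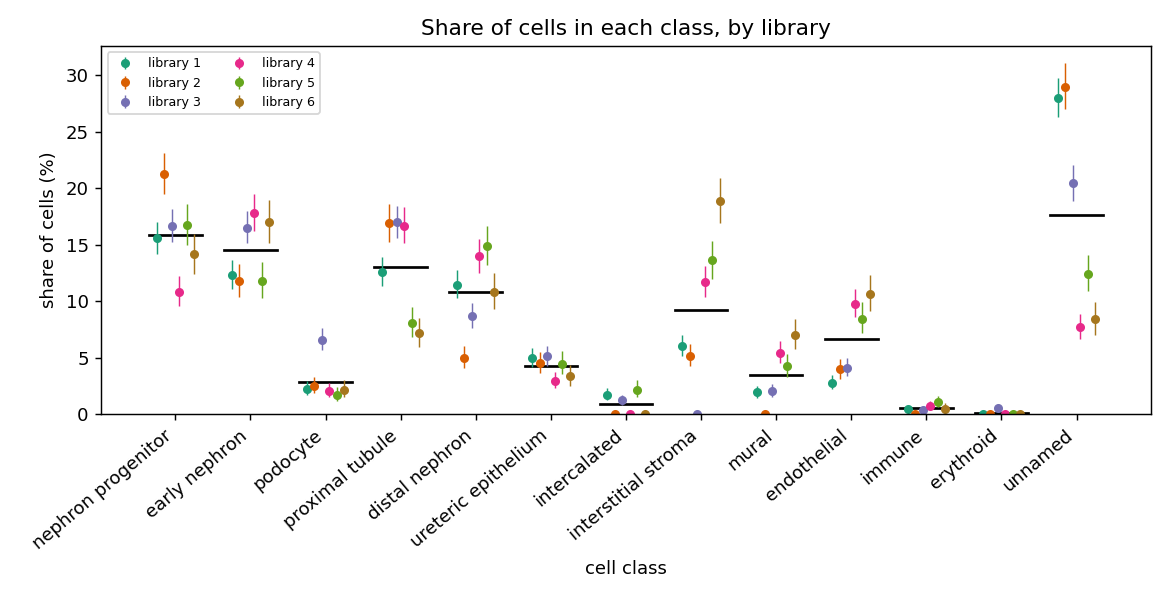
Share of cells in each class (y axis, percent) for each of the 6 libraries (coloured points, bars are exact 95% binomial intervals), with the mean over libraries as a black line. Clusters with mesothelial markers are left out; stroma lies between 0% in library 3, where no cluster was so named, and 18.9% in library 6, while nephron progenitors lie near their mean of 15.9% in most libraries.

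Stroma was set against nephron progenitors, the other mesenchymal population of the fetal kidney, to ask what marks the fibroblast lineage. Most tested genes of the interstitial matrix were higher in stroma. Col1a1, a chain of the main fibrillar collagen, was 921 ± 371 CPM in stroma and 13.9 ± 17.2 CPM in progenitors (SD, n = 5), a log2 fold change of 6.48 ± 0.47 (SE, adjusted p = 2.99e-06), and was higher in 5 of 5 libraries. Col3a1, the collagen found beside it, differed by 7.34 ± 0.48 (adjusted p = 1.64e-06, 5 of 5). Pax2, a transcription factor needed to form nephrons, was 12.0 ± 10.3 CPM in stroma against 605 ± 136 CPM, a log2 fold change of -5.75 ± 0.23 (adjusted p = 9.59e-08, lower in 5 of 5). Of 11073 genes tested, 5721 were called, 2898 higher and 2823 lower in stroma, and 2022 of these differed at least 2-fold, 1148 higher and 874 lower. The sums held 1028 stromal and 1563 progenitor cells of libraries 1, 2, 4, 5 and 6 and between 1174241 and 7272643 UMIs. Within the technical batches 3416 genes were called in libraries 1 and 2 and 5385 in libraries 4 to 6. Without library 4 the log2 fold changes of Col1a1, Col3a1, Acta2, Fap, Dkk1 and Hs3st6 were 7.29, 8.29, 6.50, 8.21, 7.52 and -7.12. Over all alternatives Col1a1 lay between 5.67 and 7.78, Col3a1 between 6.63 and 9.13, Fap between 5.09 and 8.30, Mfap5 between 6.08 and 8.46, Amph between -7.32 and -4.96, Hs3st6 between -10.89 and -4.76, Col2a1 between -6.81 and -4.96 and Uncx between -6.18 and -4.40. Acta2, Postn and Ifitm3 rose to at most 6.85, 6.23 and 5.78, and Kcnmb2 lay between -9.97 and -4.79.

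Of 28 tested genes of the interstitial matrix list, 23 were higher and 2 lower in stroma, and 24 and 2 when adjusted over the list alone (adjusted p = 1.68e-23; adjusted p = 0.157 with an estimated correlation). On the log2 scale, as for all examples that follow, Col5a1 differed by 4.11 ± 0.15 and Mfap5, a microfibril protein with 4 UMIs in progenitors, by 7.56 ± 0.29. Postn, a matrix protein of active fibroblasts, was 73.9 ± 24.3 CPM against 2.46 ± 1.86 CPM (log2 4.98 ± 0.27, adjusted p = 4.61e-07, 5 of 5). Of 12 contractile genes 10 were higher and 0 lower (adjusted p = 2.82e-13; adjusted p = 0.21 with an estimated correlation), among them Acta2, the smooth muscle actin (643 ± 470 against 11.1 ± 10.8 CPM, log2 5.85 ± 0.38, adjusted p = 1.58e-06, 5 of 5), and Cnn2 (log2 3.75 ± 0.14). Mural markers, 236 ± 48.4 CPM in stroma and 57.0 ± 27.5 CPM in progenitors, moved with this group. Of 14 genes of fibroblast activation 12 were higher and 0 lower, and 12 and 1 when adjusted over the list alone (adjusted p = 1.23e-06; adjusted p = 0.132 with an estimated correlation). Fap, a protease of activated fibroblasts, was 44.0 ± 15 CPM against 0.611 ± 1.10 CPM (log2 6.23 ± 0.57, adjusted p = 1.32e-05, 5 of 5), and Loxl1 and Ccn1 differed by 3.34 ± 0.17 and 3.25 ± 0.17. Of 13 mesenchymal genes 11 were higher and 1 lower (adjusted p = 2.6e-06; adjusted p = 0.153 with an estimated correlation). Vim, an intermediate filament, differed by 1.93 ± 0.09 (685 ± 265 against 176 ± 57.5 CPM) and Fstl1 by 2.19 ± 0.08.

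Signalling lists were mixed. Of 13 Wnt genes 6 were higher and 4 lower, and 7 and 5 adjusted over the list alone (adjusted p = 0.0272; adjusted p = 0.266 with an estimated correlation). Examples were Dkk1, a secreted Wnt inhibitor, at 134 ± 47.8 CPM in stroma against 1.19 ± 1.07 CPM (log2 6.81 ± 0.27) and Sfrp1 at 4.21 ± 0.24. Of 11 retinoid genes 5 were higher and 3 lower (adjusted p = 0.0113; adjusted p = 0.217 with an estimated correlation), Dhrs3, a retinaldehyde reductase, by 2.32 ± 0.08 and the receptor Rarb by 2.01 ± 0.08. The stromal level of Rarb varied widely between libraries, at 131 ± 100 CPM by shares of all UMIs. Of 15 immediate early genes 9 were higher and 1 lower (adjusted p = 0.012; adjusted p = 0.339 with an estimated correlation). Examples were Egr1 at 3.13 ± 0.20 and Klf6 at 2.30 ± 0.14. Of 7 interferon and MHC class I genes 6 were higher and 0 lower (adjusted p = 0.00705; adjusted p = 0.254 with an estimated correlation). Examples were Ifitm3 at 4.71 ± 0.38 and B2m at 1.27 ± 0.11. Of 17 basement membrane genes 8 were higher and 2 lower (adjusted p = 0.00558; adjusted p = 0.192 with an estimated correlation). Examples were Nid1 at 3.74 ± 0.10 and Nid2 at 2.15 ± 0.15. The Wnt call was lost without the low-count filter and with all UMIs of the same cells (adjusted p = 0.149 and 0.103). The retinoid call was lost with another random split, with clusters from markers alone and with every barcode of at least 1000 UMIs (adjusted p = 0.053, 0.13 and 0.104), and the basement membrane call with clusters from markers alone (0.112). The other lists did not pass camera's test. They were cell cycle (16 higher and 3 lower of 26, adjusted p = 0.121), glycolysis (0 and 8 of 16, 0.13), FGF response (4 and 8 of 14, 0.199). So were hypoxia (5 and 1 of 10, 0.199), Notch (1 and 3 of 6, 0.271), tubular injury (3 and 4 of 12, 0.291), hedgehog (4 and 1 of 9, 0.316). The remaining ones were epithelial junction (1 and 5 of 9, 0.326), oxidative phosphorylation (2 and 5 of 23, 0.38), distal ion transport (4 and 0 of 9, 0.0974) and fatty acid oxidation (5 and 4 of 16, 0.976). Of these, glycolysis passed in 5 of 18 alternatives (adjusted p 0.00436 to 0.0428), cell cycle in 4 (0.00409 to 0.0485), distal ion transport in 2 (0.0279 and 0.0470) and oxidative phosphorylation and hypoxia in 1 each (0.0146 and 0.0327). By fry, FGF response, glycolysis and Notch were lower (adjusted p = 0.000925, 0.00536 and 0.0169). Fry also called hypoxia, distal ion transport, tubular injury and hedgehog, as higher (adjusted p = 0.00277, 0.0106, 0.0117 and 0.0161).

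Outside the lists, Pcdh9 was among the largest rises in stroma, with a log2 change of 7.73 ± 0.36. Pcdh9 spans long introns and reached 566 to 693 CPM in libraries 1 and 2 and 16.8 to 21.6 CPM in the others, and its log2 change was 7.08 without library 2 and 5.06 in libraries 4 to 6. The largest falls were in Amph (log2 -6.74 ± 0.24), Hs3st6 (-6.52 ± 0.28), the cartilage collagen gene Col2a1 (-6.30 ± 0.32) and Uncx, a homeobox gene (-5.85 ± 0.14), and in Kcnmb2, with 3 UMIs in stroma and 2178 in progenitors (ratio 282, counting interval 96.4 to 1369). The 3 UMIs were in library 2, and without it Kcnmb2 was at least 125-fold lower in stroma. On GRCm38, Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042, Acta2 (ENSMUSG00000035783) on chromosome 19 from 34241090 to 34255590, Fap (ENSMUSG00000000392) on chromosome 2 from 62500943 to 62574075, Pax2 (ENSMUSG00000004231) on chromosome 19 from 44756045 to 44837871 and Dkk1 (ENSMUSG00000024868) on chromosome 19 from 30545863 to 30549665. Neural markers were lower in stroma (13.5 ± 10.5 against 91.9 ± 36.2 CPM, 0 of 5 libraries higher), carried by Elavl4, and skeletal muscle markers higher (77.3 ± 26.1 against 8.72 ± 2.28 CPM, 5 of 5), carried by Tnnt1.

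**Figure D2:**
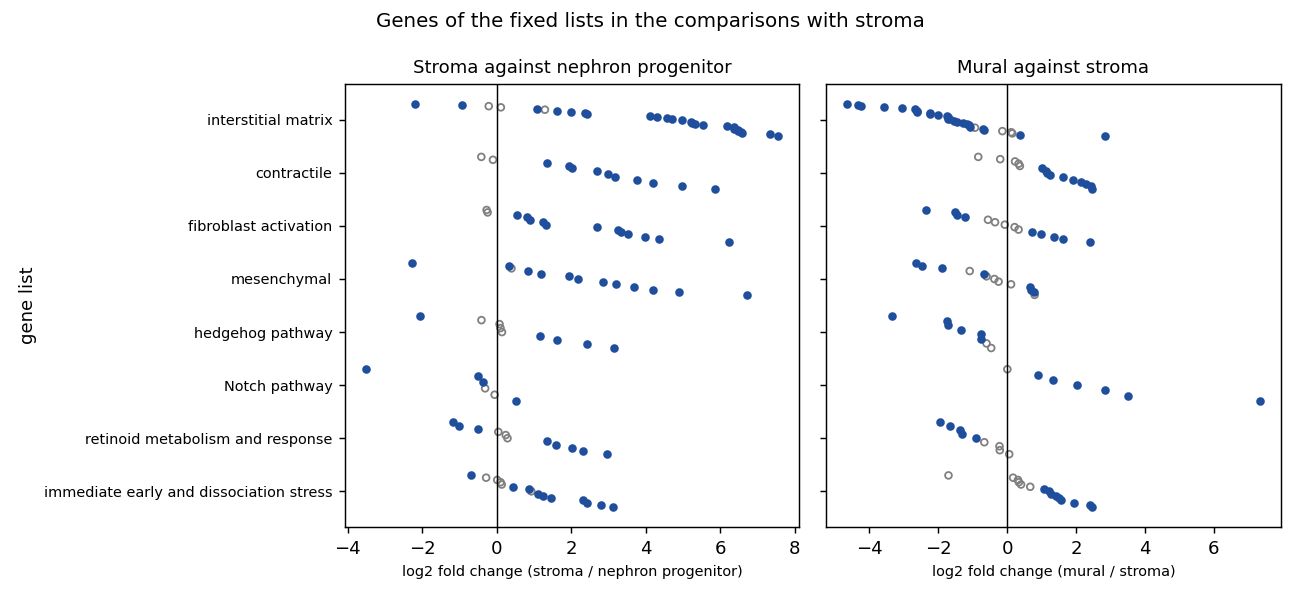
Log2 fold changes (x axis) of the tested genes of 8 lists (y axis), for stroma against nephron progenitors and for mural cells against stroma; filled points passed the test and open points did not. Most matrix genes lie to the right in the first panel and to the left in the second, with list medians of 4.84 and -1.64.

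Mural cells were set against stroma to separate contractile vessel cells from fibroblasts. Most contractile genes were higher and most matrix genes lower in mural cells. Acta2 was 2126 ± 590 CPM in mural cells and 769 ± 444 CPM in stroma (SD, n = 4), a log2 fold change of 1.62 ± 0.18 (SE, adjusted p = 0.000193, higher in 4 of 4 libraries). Col1a1 was 187 ± 117 against 1048 ± 297 CPM (log2 -2.62 ± 0.27, adjusted p = 0.000114, lower in 4 of 4). Nrarp, a feedback target of Notch, was 100 ± 37.8 against 0.511 ± 0.773 CPM (log2 7.34 ± 0.35, adjusted p = 1.62e-06, higher in 4 of 4). Of 9488 genes tested, 1509 were called, 852 higher and 657 lower in mural cells, and 903 differed at least 2-fold, 510 higher and 393 lower. The sums held 344 mural and 925 stromal cells of libraries 1, 4, 5 and 6 and between 651445 and 2468899 UMIs. The count rested on single libraries, with 995 genes without library 5 and 1041 without library 4. Within batches, libraries 4 to 6 gave 1719 genes, and the other batch held library 1 alone. Among the genes named here, Dcn, Postn and Vim lost their call in 3, 4 and 4 of 19 alternatives, with adjusted p of up to 0.341, 0.758 and 0.207, and Gli1 and Col1a1 in 1 each, with another random split of the UMIs. The values shrank as well. With another random split the log2 fold changes were -1.71 for Dcn, -1.42 for Gli1, -1.81 for Col1a1 and -0.43 for Postn. With doublets kept, which left 3 libraries, Dcn was -1.18, Col1a1 -1.57 and Postn -0.53, and with every barcode of at least 1000 UMIs Dcn was -2.33, Gli1 -1.80 and Postn -0.27. Their size is therefore not fixed by these data. Acta2, Rarb, Isg15 and H2-D1 lost it in 1 each, without the block for the library (adjusted p = 0.0771, 0.295, 0.0978 and 0.151).

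Of 29 interstitial matrix genes 22 were lower and 2 higher in mural cells, and 24 and 2 when adjusted over the list alone (adjusted p = 1.68e-23; adjusted p = 0.132 with an estimated correlation). Examples were Dcn, a small proteoglycan, at -4.34 ± 0.26 and Col6a2 at -2.62 ± 0.17. Postn was 38.6 ± 8.21 against 84.9 ± 8.40 CPM (log2 -1.15 ± 0.16, adjusted p = 0.000774, lower in 4 of 4). Of 15 contractile genes 10 were higher and 0 lower, and 11 and 1 when adjusted over the list alone (adjusted p = 1.48e-08; adjusted p = 0.324 with an estimated correlation). Examples were Tagln at 1.90 ± 0.19 and Lmod1 at 2.45 ± 0.26. Of 7 Notch genes 6 were higher and 0 lower (adjusted p = 2.82e-13; adjusted p = 0.153 with an estimated correlation), Hey2 by 3.50 ± 0.27. Endothelial markers moved with this group (300.4 ± 304 CPM in mural cells against 88.1 ± 14.5 CPM in stroma, higher in 4 of 4). In library 1 Pecam1 and Flt1 reached 90.6 and 101 CPM in mural cells against 0 to 7.21 and 0.901 to 3.58 CPM in the others. Of 8 hedgehog genes 6 were lower and 0 higher, and 7 and 0 when adjusted over the list alone (adjusted p = 2.74e-05; adjusted p = 0.244 with an estimated correlation). Examples were the pathway target Gli1 at -3.33 ± 0.40 and the coreceptor Gas1 at -1.74 ± 0.17. Of 9 retinoid genes 5 were lower and 0 higher (adjusted p = 4.34e-05; adjusted p = 0.153 with an estimated correlation). One of them was Rarb at -1.36 ± 0.17. Of 15 immediate early genes 9 were higher and 0 lower, and 11 and 1 when adjusted over the list alone (adjusted p = 0.000215; adjusted p = 0.28 with an estimated correlation). Examples were Nr4a1 at 2.47 ± 0.35 and Dusp1 at 2.41 ± 0.35. Of 8 interferon genes 5 were higher and 0 lower, and 7 and 0 when adjusted over the list alone (adjusted p = 0.00152; adjusted p = 0.313 with an estimated correlation). Examples were Isg15 at 2.01 ± 0.26 and H2-D1 at 0.99 ± 0.19. Of 13 mesenchymal genes 3 were higher and 4 lower (adjusted p = 0.0155; adjusted p = 0.244 with an estimated correlation). Examples were Cdh11 at -2.49 ± 0.19 and Snai2 at -1.89 ± 0.14, whereas Vim was higher (1257 ± 369 against 769 ± 227 CPM, log2 0.70 ± 0.20, adjusted p = 0.0395, 4 of 4). The call of the mesenchymal list was lost in 5 of 17 alternatives, with adjusted p of 0.0604 to 0.438.

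Fibroblast activation did not pass the test, with 5 genes higher and 4 lower of 14 (adjusted p = 0.658). Fap was 26.3 ± 4.86 CPM in mural cells and 40.7 ± 14.8 CPM in stroma (log2 -0.56 ± 0.21, adjusted p = 0.116, lower in 3 of 4 with TMM factors and in 4 of 4 by shares of all UMIs), but passed with clusters from markers alone (log2 -1.05, adjusted p = 0.00266). The other lists that did not pass were basement membrane (7 higher and 2 lower of 17, 0.0717), Wnt (2 and 6 of 12, 0.171), hypoxia (3 and 5 of 10, 0.214), fatty acid oxidation (1 and 2 of 16, 0.278). Cell cycle (0 and 0 of 26, 0.316) did not pass either. The same held for distal ion transport (1 and 0 of 8, 0.433), epithelial junction (1 and 0 of 6, 0.612), oxidative phosphorylation (2 and 1 of 23, 0.883), glycolysis (1 and 0 of 16, 0.899), tubular injury (1 and 1 of 7, 0.948) and FGF response (2 and 2 of 11, 0.956). Glycolysis had a median log2 fold change of -0.11, a mean of 0.01 and a test pointing down, tubular injury -0.04, 0.10 and up, and FGF response 0.09, 0.08 and down. Of these lists basement membrane passed in 6 of 17 alternatives (higher, adjusted p 0.0107 to 0.0474), cell cycle in 4 (lower, 0.0159 to 0.0351) and Wnt in 3 (lower, 0.0276 to 0.0447). Fry called basement membrane and fatty acid oxidation higher (adjusted p = 0.00571 and 0.00167) and Wnt lower (adjusted p = 0.000799). Among the largest changes, Dgkb had 226 UMIs in mural cells and 2 in stroma (ratio 249, counting interval 68.3 to 2072) and Nrxn3 had 2 and 474 (ratio 107 in the other direction, 29.6 to 889). Both have long introns. Dgkb was 262 CPM in mural cells of library 1 and 10.6 to 26.1 CPM in the others, and Nrxn3 199.7 CPM in stroma of library 1 and 20.4 to 31.2 CPM in the others. The ratio of Dgkb was 122 (21.0 to 4902) without library 1 and 435 (77.1 to 17257) without library 6, and that of Nrxn3 87.1 without library 1 and 188 (33.6 to 7446) without library 5. Serpini1 (log2 6.25 ± 0.23), Mustn1 (7.03 ± 0.31) and Gja5, a gap junction protein of vessels (6.06 ± 0.44), were higher, and Nts, a neuropeptide (-6.60 ± 0.30), and Col15a1 (-4.01 ± 0.33) lower. In mural cells of library 1 Gja5 stood at 109 CPM, against 12.5 to 68.4 CPM in the others, and its log2 fold change was 6.86 without library 1 and 5.41 without library 4. Without single libraries the values were 8.62 for Nrarp (library 4), 7.68 for Mustn1 (library 5) and -7.36 for Nts (library 6). Over all alternatives Nrarp was at least 5.99, Nts at most -4.63, Dgkb at least 5.07 and Nrxn3 between -9.67 and -4.37. Nrarp (ENSMUSG00000078202) lies on chromosome 2 from 25180758 to 25183339. Ureteric markers were higher in mural cells (358 ± 137 against 49.5 ± 14 CPM, 4 of 4), carried by Gata3, and so were podocyte markers (121 ± 64.2 against 68.8 ± 50.8 CPM, 4 of 4), carried by Synpo.

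The distal nephron was set against the proximal tubule, since the series concerns the distal tubule. The markers of this distal class cover thick limb and distal tubule together, so its levels are not those of the distal tubule alone. Distal nephron and proximal tubule each had higher levels of their own transporters. Since the classes were named by markers of these segments, this follows in part from the naming. Kcnj1, the potassium channel of the thick limb, was 187 ± 84.8 CPM in distal cells and 1.03 ± 0.863 CPM in proximal cells (SD, n = 6), a log2 fold change of 7.61 ± 0.32 (SE, adjusted p = 5.45e-07, higher in 6 of 6 libraries). Slc22a6, an organic anion carrier, was 3.0 ± 2.11 against 464 ± 203 CPM (log2 -7.31 ± 0.21, adjusted p = 2.58e-07, lower in 6 of 6). Sox9, a transcription factor of growing and repairing tubules, was 80.1 ± 44.2 against 1.49 ± 1.18 CPM (log2 5.53 ± 0.34, adjusted p = 3.52e-06, higher in 6 of 6), and Vcam1, an adhesion protein, 2.69 ± 2.53 against 80.1 ± 22.3 CPM (log2 -4.95 ± 0.44, adjusted p = 2.32e-05, lower in 6 of 6). Of 12024 genes tested, 6685 were called, 3437 higher and 3248 lower in distal cells, and 3144 differed at least 2-fold, 1728 higher and 1416 lower. The sums held 1342 distal and 1720 proximal cells and between 2047207 and 9020739 UMIs. Within batches, libraries 1 and 2 gave 1694 genes and libraries 4 to 6 gave 5351. Plk1, Krt8 and Clu lost their call in libraries 1 and 2 alone (adjusted p = 0.186, 0.0733 and 0.225), and Vcam1 was -5.66 without library 1. Over all alternatives Vcam1 lay between -6.81 and -3.61, Sox9 between 4.31 and 6.24, Kcnj1 between 6.85 and 9.31, Plk1 between 1.07 and 3.27, Cldn8 between 3.97 and 6.14 and Slc5a12 between -9.24 and -7.40. Pappa2 lay between 7.40 and 10.07, Tmem72 between 6.95 and 8.83, Ugt2b34 between -9.07 and -6.58 and Ugt2b37 between -9.76 and -6.93. With every barcode of at least 1000 UMIs 6400 of the called genes were tested again, and 5046 were called in the same direction. The fold change of 172 had the other sign, whether called there or not.

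Of 24 genes of proximal tubule transport 23 were lower and 1 higher in distal cells (adjusted p = 3.35e-35; adjusted p = 0.134 with an estimated correlation). Examples were Slc5a12 at -8.09 ± 0.26 and Abcc2 at -7.73 ± 0.23. Of 20 genes of thick limb and distal tubule ion transport 15 were higher and 0 lower (adjusted p = 1.53e-13; adjusted p = 0.153 with an estimated correlation). Examples were the calcium sensor Casr at 7.05 ± 0.26 and Cldn8 at 5.25 ± 0.19. Of 25 junction and polarity genes 17 were higher and 2 lower (adjusted p = 3.27e-07; adjusted p = 0.217 with an estimated correlation). Examples were the splicing factor Esrp1 at 5.19 ± 0.17 and the protease St14 at 2.14 ± 0.09. Of 26 cell cycle genes 25 were higher and 0 lower (adjusted p = 0.00043; adjusted p = 0.648 with an estimated correlation). Examples were Rrm2 at 2.87 ± 0.29 and Plk1 at 2.59 ± 0.42. Of 13 genes of the FGF response 10 were higher and 1 lower (adjusted p = 0.00104; adjusted p = 0.254 with an estimated correlation). Examples were Fgf9 at 5.07 ± 0.33 and Etv5 at 3.52 ± 0.26. Early nephron markers were 423 ± 203 CPM in distal and 277 ± 74.2 CPM in proximal cells, higher in 4 of 6 libraries only. Ureteric markers were 163 ± 121 against 10.7 ± 3.20 CPM (6 of 6). Of 19 genes of fatty acid oxidation 12 were lower and 1 higher (adjusted p = 0.00701; adjusted p = 0.658 with an estimated correlation). Examples were Decr1 at -1.17 ± 0.08 and Ehhadh at -3.33 ± 0.26, and of 17 glycolysis genes 11 were higher and 2 lower, and 11 and 3 when adjusted over the list alone (adjusted p = 0.0293; adjusted p = 0.503 with an estimated correlation). Examples were Pkm at 2.44 ± 0.13 and Hk1 at 5.41 ± 0.32. The calls of cell cycle and fatty acid oxidation were lost with every barcode of at least 1000 UMIs (adjusted p = 0.223 and 0.531), and that of glycolysis with doublets kept, at resolution 2 and without library 2 (0.0564, 0.0757 and 0.0574). The mitochondrial share was 8.16% ± 1.03 in distal and 9.68% ± 1.54 in proximal cells.

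Tubular injury genes went both ways, with 4 higher and 5 lower of 14 (adjusted p = 0.723). Krt8 was 143 ± 38.2 against 319 ± 97.8 CPM (log2 -1.13 ± 0.17, adjusted p = 0.000499, lower in 6 of 6) and Clu, a secreted chaperone, 86.2 ± 35.3 against 174 ± 20.9 CPM (log2 -1.09 ± 0.19, adjusted p = 0.00133, lower in 6 of 6). Spp1 (osteopontin) was 331 ± 144 against 271 ± 124 CPM and did not pass (log2 0.24 ± 0.27, adjusted p = 0.475, higher in 3 of 6 with TMM factors and in 5 of 6 by shares of all UMIs), but passed with every barcode of at least 1000 UMIs (adjusted p = 0.00338). The classical injury genes were near the detection limit and were not tested. Havcr1 was 0.379 ± 0.461 CPM in proximal cells (11 UMIs) and 0.0577 CPM in distal cells (2 UMIs), Lcn2 0.428 ± 0.653 CPM (11 UMIs) and 0.369 ± 0.430 CPM (12 UMIs), and Krt20 1.44 ± 1.29 CPM (61 UMIs) and 0.118 CPM (2 UMIs). The other lists that did not pass were hedgehog (4 higher and 0 lower of 6, 0.094), Wnt (9 and 3 of 13, 0.102), immediate early (6 and 0 of 15, 0.17), interferon (4 and 2 of 8, 0.247). Not passed either were hypoxia (2 and 4 of 10, 0.269), Notch (1 and 0 of 7, 0.468), matrix (4 and 4 of 16, 0.847), basement membrane (4 and 7 of 17, 0.899), contractile (2 and 2 of 9, 0.899). The last ones were retinoid (3 and 3 of 8, 0.956), mesenchymal (1 and 1 of 6, 0.957), oxidative phosphorylation (1 and 2 of 23, 0.957) and fibroblast activation (2 and 2 of 9, 0.971). The Wnt list passed in 7 of 19 alternatives (higher, adjusted p 0.00314 to 0.0471) and the immediate early list in 1 (0.0440). With fry, hedgehog, Wnt, immediate early and interferon genes were higher (adjusted p = 0.000302, 0.00178, 0.00201 and 0.0212) and hypoxia genes lower (adjusted p = 0.00329). Oxidative phosphorylation turned to higher in distal cells with every barcode of at least 1000 UMIs (adjusted p = 0.00255). Medians, means and tests differed in sign for matrix (-0.20, 0.14, up), injury (-0.30, 0.02, down), mesenchymal (-0.20, 0.12, down), contractile (-0.01, -0.08, up) and retinoid genes (0.02, -0.12, up). Further large rises were Pappa2, a protease of growth factor binding proteins (log2 8.70 ± 0.40, and 9.40 without library 4), Sfrp1 (7.58 ± 0.36) and Tmem72 (7.45 ± 0.25), and further falls Ugt2b34 (-8.59 ± 0.27) and Ugt2b37 (-8.23 ± 0.36), close relatives that can share reads. Kcnj1 (ENSMUSG00000041248) lies on chromosome 9 from 32372493 to 32399197, Slc22a6 (ENSMUSG00000024650) on chromosome 19 from 8618039 to 8628299, Vcam1 (ENSMUSG00000027962) on chromosome 3 from 116109949 to 116129688 and Sox9 (ENSMUSG00000000567) on chromosome 11 from 112782224 to 112787760. Mesothelial markers were lower in distal cells (44.1 ± 18.6 against 127 ± 38.1 CPM, 0 of 6 higher), carried by Gpm6a, and liver markers as well (111 ± 49.8 against 205 ± 59.4 CPM, 1 of 6 higher), carried by Afp.

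**Figure D3:**
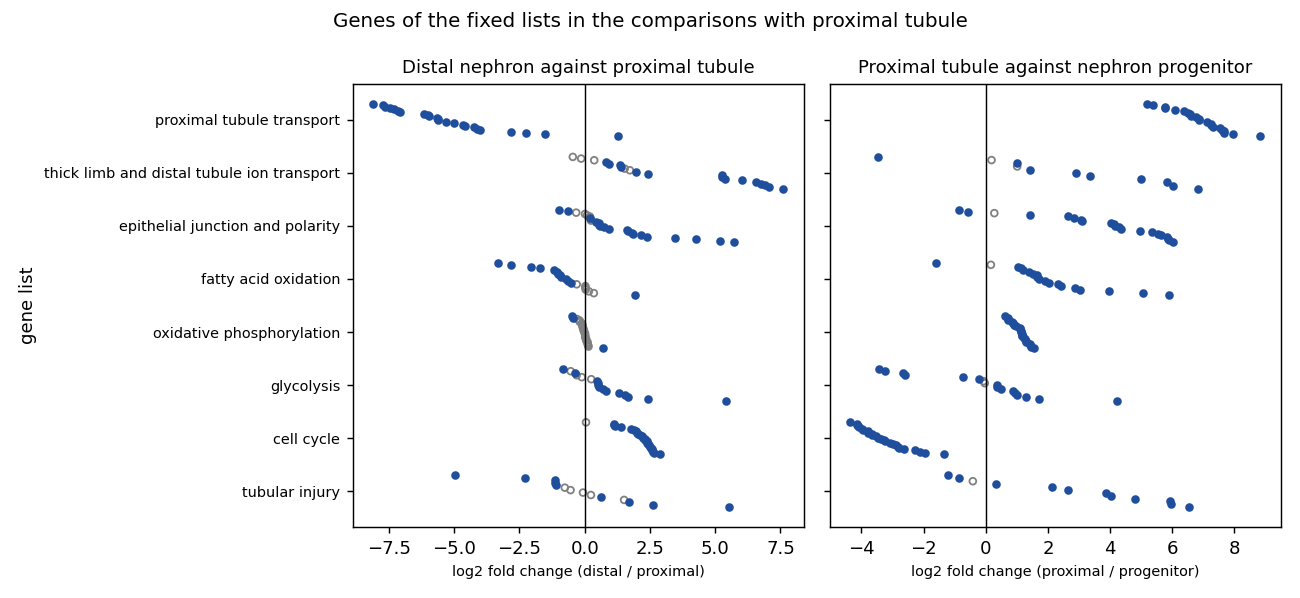
Log2 fold changes (x axis) of the tested genes of 8 lists (y axis), for the distal nephron against the proximal tubule and for the proximal tubule against nephron progenitors; filled points passed the test and open points did not. In the second panel cell cycle genes lie left of 0 and genes of proximal transport right of it, with medians of -3.42 and 6.87.

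The proximal tubule was set against nephron progenitors, the cells from which it forms. Most genes of proximal transport, fatty acid oxidation and oxidative phosphorylation were higher in the tubule and genes of cell division lower, but of these lists only proximal transport was called with an estimated correlation as well, and glycolysis did not pass. Slc2a2, the glucose transporter of the basal membrane, was 172 ± 13.2 CPM in the tubule and 0.811 ± 0.324 CPM in progenitors (SD, n = 6), a log2 fold change of 7.67 ± 0.14 (SE, adjusted p = 4.12e-12, higher in 6 of 6 libraries). Acadm, an enzyme of fatty acid oxidation, was 781 ± 175 against 49.4 ± 9.27 CPM (log2 3.97 ± 0.10, adjusted p = 2.4e-11, 6 of 6), and Aurkb, a mitotic kinase, 3.25 ± 1.16 against 50.7 ± 7.84 CPM (log2 -4.07 ± 0.14, adjusted p = 1.82e-10, lower in 6 of 6). Of 11932 genes tested, 9396 were called, 4579 higher and 4817 lower in the tubule, and 4916 differed at least 2-fold, 2588 higher and 2328 lower. The sums held 1720 tubule and 2001 progenitor cells and between 2047207 and 9020739 UMIs. Within batches, libraries 1 and 2 gave 9409 genes and libraries 4 to 6 gave 8491. Over all alternatives Aurkb lay between -4.36 and -2.51, Vcam1 between 5.85 and 7.73, Fbn2 between -6.18 and -4.84, Zeb1 between -6.35 and -5.02, Slc17a3 between 7.49 and 10.02 and Slc7a12 between 7.99 and 9.73.

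Proximal transport was the one list called with an estimated correlation as well, with 22 of 22 genes higher (adjusted p = 3.57e-30; adjusted p = 0.0426 with an estimated correlation). Because the tubule class was named by markers of the same segment, this rise follows in part from the naming. Of 19 genes of fatty acid oxidation 17 were higher and 1 lower (adjusted p = 3.27e-07; adjusted p = 0.153 with an estimated correlation). All 23 genes of oxidative phosphorylation were higher (adjusted p = 1.92e-05; adjusted p = 0.462 with an estimated correlation). Examples were Cox7b at 1.41 ± 0.07 and Cox5a at 1.55 ± 0.08, and the mitochondrial share was 9.68% ± 1.54 against 6.16% ± 0.506 (6 of 6). Of 21 junction genes 18 were higher and 2 lower (adjusted p = 2.46e-12; adjusted p = 0.16 with an estimated correlation). Examples were Cldn6 at 6.03 ± 0.10 and Cdh16 at 5.83 ± 0.12. Of 11 distal ion transport genes 8 were higher and 1 lower (adjusted p = 7.51e-05; adjusted p = 0.132 with an estimated correlation). Kcnj16 was among them at 6.04 ± 0.16. Of 17 basement membrane genes 14 were higher and 2 lower (adjusted p = 0.00138; adjusted p = 0.217 with an estimated correlation). Examples were Npnt at 5.96 ± 0.16 and Lama1 at 4.65 ± 0.13.

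Of 12 tubular injury genes 9 were higher and 2 lower in the tubule (adjusted p = 3.35e-05; adjusted p = 0.134 with an estimated correlation), in kidneys without a stated injury. Krt8 was 309 ± 91.9 against 5.0 ± 2.03 CPM (log2 5.97 ± 0.10), Cdkn1a, a cell cycle inhibitor, 239 ± 80.7 against 8.48 ± 3.40 CPM (4.80 ± 0.11), Vcam1 77.8 ± 21.2 against 0.930 ± 0.931 CPM (6.55 ± 0.27, and 7.19 without library 6), Spp1 263 ± 121 against 4.75 ± 3.55 CPM (5.93 ± 0.24) and Clu 169 ± 21.0 against 12.0 ± 3.44 CPM (3.86 ± 0.15), each higher in 6 of 6 libraries. Sox9 was 1.45 ± 1.16 against 3.71 ± 1.62 CPM (log2 -1.20 ± 0.41, adjusted p = 0.0191, lower in 5 of 6), a call lost in 7 of 21 alternatives (adjusted p 0.0517 to 0.252 there). By shares of all UMIs it was lower in 6 of 6. Havcr1, Lcn2 and Krt20 did not pass the low-count filter here either. In progenitors Lcn2 reached 114 CPM in library 5 and 0 to 0.825 CPM in the others, as did Lyz2, an immune marker, with 96.7 CPM against 0.138 to 0.959 CPM.

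All 26 cell cycle genes were lower in the tubule (adjusted p = 7.84e-10; adjusted p = 0.342 with an estimated correlation), Hmgb2 by a log2 fold change of -2.89 ± 0.13. Of 20 matrix genes 14 were lower and 2 higher, and 15 and 2 when adjusted over the list alone (adjusted p = 0.002; adjusted p = 0.266 with an estimated correlation). Examples were Fbn2 at -5.96 ± 0.20. Of 11 contractile genes 9 were lower and 1 higher (adjusted p = 0.0284; adjusted p = 0.217 with an estimated correlation). Tpm2 was at -6.02 ± 0.31, and the call was lost with doublets kept and at resolution 2 (adjusted p = 0.0728 and 0.0776). Of 10 mesenchymal genes 9 were lower and 1 higher (adjusted p = 0.00043; adjusted p = 0.266 with an estimated correlation). Examples were Zeb1 at -6.12 ± 0.19 and Cdh2 at -5.20 ± 0.19. Markers of interstitial stroma, 111 ± 53.8 CPM in the tubule and 1077 ± 602 CPM in progenitors (0 of 6 higher), moved with the matrix, contractile and mesenchymal genes. All 6 hedgehog genes were lower (adjusted p = 0.0024; adjusted p = 0.244 with an estimated correlation), Gas1 at -4.19 ± 0.13, and 13 of 14 genes of the FGF response were lower and 1 higher (adjusted p = 2.74e-05; adjusted p = 0.266 with an estimated correlation), Etv4 at -5.46 ± 0.16. The lists that did not pass were retinoid (2 higher and 7 lower of 11, 0.0853), hypoxia (7 and 2 of 10, 0.0863), fibroblast activation (3 and 6 of 11, 0.105), Wnt (1 and 8 of 11, 0.155). Neither did Notch (0 and 5 of 8, 0.243), interferon (4 and 2 of 7, 0.899), glycolysis (9 and 6 of 17, 0.939) and immediate early genes (6 and 4 of 15, 0.974). Retinoid genes passed in 1 alternative, with every barcode of at least 1000 UMIs (0.0338), and fibroblast activation in 1, without the block (0.0297). Fry called retinoid, fibroblast activation, Wnt and Notch genes lower (adjusted p = 4.04e-05, 0.000331, 0.000263 and 0.00461). Hypoxia and interferon genes were higher by fry (adjusted p = 2.65e-05 and 0.00486). Glycolysis had a median of 0.35, a mean of -0.10 and a test pointing down, and immediate early genes 0.23, 0.13 and down. Largest rises included Slc17a3 (log2 8.83 ± 0.28, and 9.56 without library 4), Slc7a12 (8.62 ± 0.16) and Sult1d1, a sulfotransferase (8.22 ± 0.19), and a large fall was Has2, which makes hyaluronan (-7.45 ± 0.29). Slc2a2 (ENSMUSG00000027690) lies on chromosome 3 from 28697903 to 28731359. Liver markers were higher in the tubule (205 ± 59.4 against 2.56 ± 0.448 CPM, 6 of 6), carried by Afp, and neural markers lower (14.6 ± 6.06 against 85.5 ± 36.0 CPM, 0 of 6), carried by Elavl4.

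**Figure D4:**
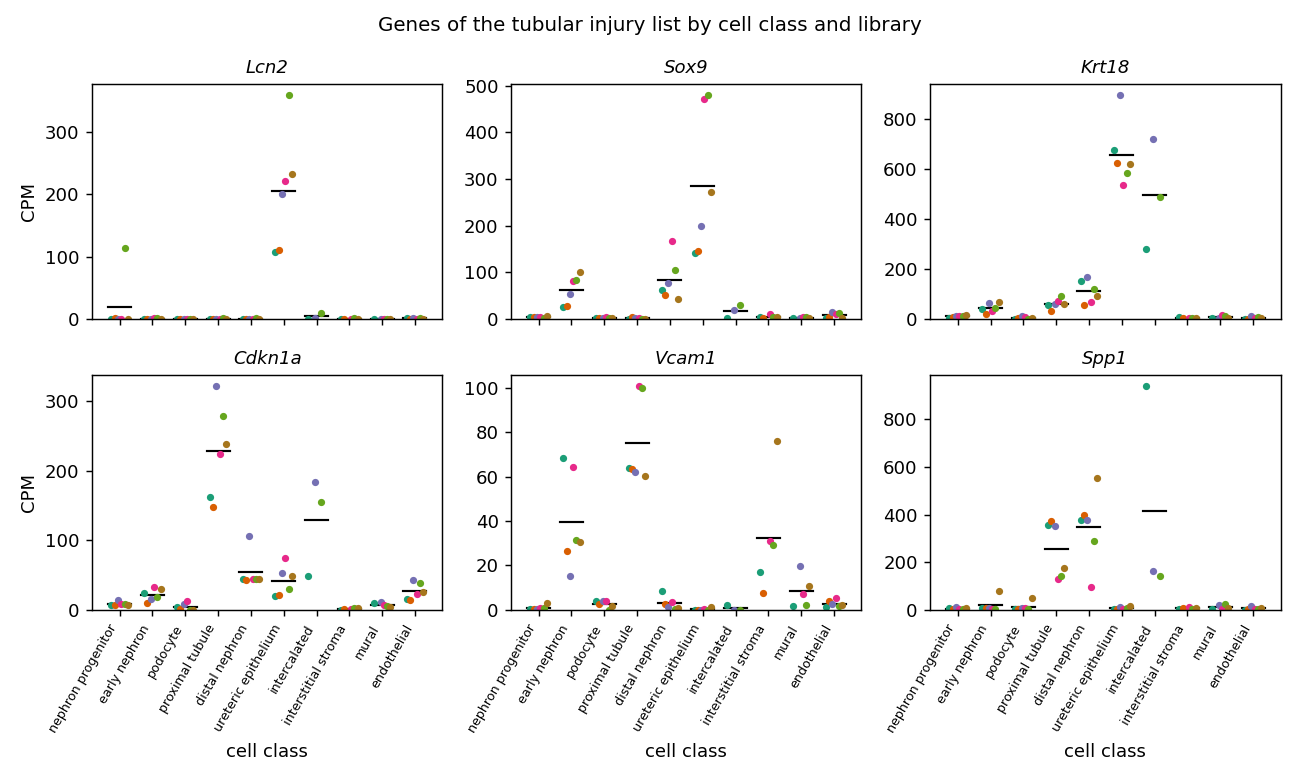
Levels of 6 genes of the tubular injury list (y axis, CPM) in 10 cell classes (x axis); points are libraries, coloured as in the plot of class shares, and lines are means over libraries with at least 20 cells of the class. Cdkn1a and Vcam1 have their highest means in the proximal tubule, at 229 and 75.1 CPM.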

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

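The tests on nuclei, on the UMI cutoff, on enrichment by EYFP, on free EYFP RNA and on swapped class labels were chosen after the result was seen, while those on intron reads, on the mix of classes and on broken cells were set before. Of 170 groups of values tested for a library far from the others, 12 had one, and chance gives about 1 in 20.

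The ratios of single libraries given here had 1 CPM added to both classes. Those of genes with a low level in either class are therefore smaller than the fitted fold changes. In stroma against nephron progenitors the log2 ratio of Mfap5 was 2.61 in library 2 and 5.13 to 5.74 in the others, and that of Fap was 2.73 in library 4 and 5.15 to 5.89 in the others. In distal against proximal cells, St14 stood at 2.61 in library 3 (others 2.11 to 2.20). In proximal tubule against progenitors, library 2 stood apart for Fat3 (-8.18, others -6.01 to -4.75) and Kcnmb2 (-6.90, others -5.10 to -4.42). In the same comparison Mfap4 was -3.92 in library 4 (others -5.37 to -5.13), Etv4 -5.70 in library 5 (others -4.86 to -4.62) and Vcam1 3.99 in library 6 (others 5.41 to 5.81). Podocytes made up 6.58% of library 3 and 1.69% to 2.5% of the others, and erythroid cells 0.533% of library 3 and 0% of the others.

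Long genes were higher in libraries 1 and 2, which were counted on the longer gene list. Genes with over 100 kb of introns held 15.7% and 15.2% of the UMIs there against 5.42%, 5.93%, 5.77% and 6.1% in libraries 3 to 6. In nephron progenitors their median log2 ratio exceeded that of genes without introns by 1.94, a value that counting of intron reads in these libraries alone may give. A different mix of classes is argued against, since the difference was at least 1.77 within each of 3 classes, and nuclei in place of cells as well, since the mitochondrial share was 0.955 times the lowest of the others. No biological explanation was tested, since the labels give 1 group. Of the 152 results for named genes, 35 concern genes with over 100 kb of introns, so their CPM can depend on the library.

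Library 3 held no cluster named stroma. With every barcode of at least 1000 UMIs 96 of its cells were named stroma, so the missing cluster depends on the UMI cutoff. The cutoff does not account for the low share, which was still 2.16% there against at least 12.7% in the others. For stromal cells that broke open, the test was the level of stromal genes in its empty droplets, 298 CPM against at least 481 CPM in the others. That level was lower, but so was the share of stromal cells. It therefore cannot decide whether some of them broke open. Enrichment of cells by the EYFP reporter would have put nephron lineage classes above empty droplets, and this was not seen. EYFP there was 2.70 per 1e+06 UMIs (counting interval 2.27 to 3.20) against 2.67 in empty droplets. It was not below that level either, which was the bound set against enrichment, so the test does not decide.

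EYFP, a reporter listed for library 3 alone, gave a signal outside the main measurement in a library labelled wild-type. In ureteric epithelium it was 8.11 per 1e+06 UMIs (counting interval 5.82 to 11) against 2.67 (1.97 to 3.52) in empty droplets, so free RNA alone is argued against. It was found in 22.4% of the 134 ureteric cells and 8.33% of the endothelial cells, which lie at the level of empty droplets with 2.63 per 1e+06 UMIs. Intercalated cells stood at 6.02 per 1e+06 UMIs (2.21 to 13.1, 32 cells) and distal nephron at 3.34 (2.22 to 4.83). Both of these intervals overlap that of empty droplets. Why a reporter is present was not tested.

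With class labels swapped within libraries, 1 of the splits of each comparison, the real one, gave as many genes. It gave 5721, 1509, 6685 and 9396 genes in the 4 comparisons, and the highest other split 0. The 16 splits of stroma against progenitors and the 8 of mural cells against stroma are too few for a share under 0.05. The 32 splits of each of the others exclude nothing, since classes built by clustering the same cells fix this outcome.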

How the results depend on the processing

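The settings chosen after seeing the data were every barcode with at least 1000 UMIs for the gene tests, the clustering, filter and random split settings for lists and named genes, the batches for named genes, and the first naming of clusters. Counts of called genes stayed within 1.5 times of the reported count in 77 alternatives, summed over the 4 comparisons, but a similar count can hide turned genes. Genes are counted as turned here when their fold change had the other sign, whether called there or not. With every barcode of at least 1000 UMIs 172 of the called genes of distal against proximal cells turned, and 14, 3 and 6 of those of the other comparisons. In libraries 1 and 2 alone 24 turned for stroma against progenitors and 18 for distal against proximal cells. For the proximal tubule against progenitors 31 turned there, and 10 in libraries 4 to 6 alone. Libraries 1 and 2 alone gave 3416 genes for stroma against progenitors and 1694 for distal against proximal cells, with fewer samples than the full set. For mural cells against stroma, 1 joint clustering gave 2570 genes and every barcode with at least 1000 UMIs 3114, with 5 and 6 libraries in place of 4; the cause was not tested. Resolution 2 used 5 libraries there and doublets kept 3. Leaving out each library gave 4787 to 5521, 995 to 1719, 5708 to 6995 and 8908 to 9301 genes in the 4 comparisons, and the lowest value of mural against stroma was without library 5. Without the block for the library, the replicate block of the design, 2976 genes were called for stroma against progenitors and 641 for mural cells against stroma; the pairing within libraries is part of the design. Naming without the pair of later rules gave 5721, 1509, 6685 and 9396 genes, as reported, and moved 1 class, intercalated cells, to 2.63%. The later rules left the 4 comparisons untouched, so these equal counts say nothing about stability. Of the list tests, 1441 kept their direction and side of the threshold, 36 passed it newly, 18 lost it and 1 turned: oxidative phosphorylation in distal against proximal cells was higher, with a mean log2 fold change of 0.50 (adjusted p = 0.00255, range over its alternatives 0.00255 to 0.971), with every barcode of at least 1000 UMIs; the cause was not tested. Of the fold changes of named genes 3162 kept their call, 27 lost it and 2 gained it. Class shares depended most on cell calling. With every barcode of at least 1000 UMIs they were 12.3% for nephron progenitors, 9.23% for early nephron, 6.22% for podocytes, 5.82% for distal nephron, 3.08% for ureteric epithelium, 16.8% for stroma, 1.92% for immune and 0.824% for erythroid cells. With another random split immune cells were 1.06% and erythroid cells 0.830%. With doublets kept early nephron was 11.6% and erythroid 1.09%. Erythroid cells were 0.319% with clusters from markers alone and 0.963% at resolution 2. The proximal tubule, whose cells had a median mitochondrial share of 9.68% ± 1.54, made up 8.14% with at most 10% mitochondrial UMIs. Asking for at least 1000 genes per cell left the counts of called genes as reported, since nearly every cell of the compared classes passed it, so it says nothing about stability.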

Other observations

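Some genes of the injury and fibroblast lists were highest in the same class in most or all libraries, and those named here were chosen after their values were seen. A class had to hold at least 20 cells in a library, so immune cells, with at most 17, were not compared here or in the next paragraph, and "highest" means among the other classes. Others were not, such as Plin2 (33.8 ± 19.1 CPM in podocytes and 31.8 ± 8.97 CPM in endothelial cells) and Timp1 (21.1 ± 2.43 CPM in stroma and 19.5 ± 4.24 CPM in endothelial cells). Loxl1 was highest in stroma in 3 of 5, at nearly the level of podocytes (112 ± 14.2 and 109.7 ± 34.4 CPM). Lcn2 was highest in ureteric epithelium with 205 ± 93.4 CPM (SD, n = 6), as were Sox9 with 285 ± 155 CPM and Krt18 with 656 ± 127 CPM, each in 6 of 6 libraries. Cdkn1a (229 ± 66.6 CPM) and Tnfrsf12a (42.0 ± 11.1 CPM) were highest in the proximal tubule in 6 of 6. Clu was highest in early nephron cells in 5 of 6 (327 ± 69.5 CPM). Of the genes of fibroblast activation, Fap and Mmp2 were highest in stroma (43.7 ± 15.3 and 86.3 ± 29.2 CPM, 5 of 5), Aspn and Ccn2 in mural cells (87.6 ± 29.0 and 126 ± 39.7 CPM, 5 of 5), Tgfb1 in endothelial cells (217 ± 60.3 CPM, 6 of 6), Loxl2 in podocytes (447 ± 240 CPM, 6 of 6) and Tgfbi in nephron progenitors (160 ± 54.5 CPM, 6 of 6). For Tgfbi stroma was close behind, at 141 ± 26.3 CPM, and library 3 had no stroma class to compare.

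Among retinoid genes, a pair of enzymes that make retinoic acid differed in their classes. Aldh1a2 was 297 ± 84.0 CPM in early nephron cells (highest in 4 of 6), 286 ± 119 CPM in stroma and 4.45 ± 3.34 CPM in ureteric epithelium. Aldh1a3 was highest in ureteric epithelium (144 ± 28.0 CPM, 6 of 6), and Cyp26b1, which breaks it down, in endothelial cells (157 ± 34.6 CPM, 6 of 6). Dhrs3 was highest in stroma (117 ± 25.4 CPM, 5 of 5) and Rdh10 in nephron progenitors (51.9 ± 4.09 CPM, 6 of 6).

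Markers of other cell types were summed in the compared classes. In stroma and progenitors the sums were, in CPM, 77.7 ± 48.3 and 89.6 ± 80.5 for podocyte, 88.5 ± 53.1 and 57.6 ± 15.6 for proximal tubule, 34.4 ± 18.4 and 45.2 ± 10.5 for distal nephron and 42.3 ± 20.1 and 40.3 ± 4.54 for ureteric markers. They were 6.19 ± 2.12 and 2.33 ± 1.13 for intercalated, 82.1 ± 18.4 and 37.1 ± 14.7 for endothelial, 5.96 ± 2.71 and 30 ± 55.1 for immune and 440.1 ± 556 and 385 ± 514 for erythroid markers. Adrenal cortex markers were 8.52 ± 4.06 and 3.60 ± 1.15, mesothelial ones 27.0 ± 54.0 and 3.40 ± 1.23 and liver ones 3.74 ± 3.82 and 2.45 ± 0.397. Early nephron markers were lower in stroma in 5 of 5 libraries (89.1 ± 60.5 and 356 ± 113 CPM, adjusted p = 0.00359; adjusted p = 0.20 with an estimated correlation). In mural cells and stroma, sums with the same direction in every library, beside those of the report, were 55.1 ± 24.6 and 94.6 ± 59.3 CPM for proximal tubule and 3.98 ± 0.983 and 5.61 ± 1.93 CPM for intercalated markers. In distal and proximal cells they were 55.1 ± 31.3 and 111 ± 53.8 CPM for interstitial stroma markers. In the proximal tubule and progenitors they were 10.7 ± 3.20 and 39.4 ± 4.55 CPM for ureteric, 6.08 ± 2.94 and 2.38 ± 1.02 CPM for intercalated, 1.36 ± 0.818 and 3.48 ± 1.07 CPM for adrenal cortex, 127 ± 38.1 and 3.55 ± 1.16 CPM for mesothelial and 4.50 ± 0.965 and 8.74 ± 2.04 CPM for skeletal muscle markers. The sums not given here or in the report differed in direction between libraries. Hbb-bs, a hemoglobin gene, reached 6053, 4967, 10513, 505, 478 and 2863 CPM in the empty droplets of libraries 1 to 6.

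Sex genes separated the libraries. Xist reached 1006 and 1640 CPM in libraries 2 and 4, and Ddx3y, on the Y chromosome, 59.8, 60.3, 72.1 and 77.5 CPM in libraries 1, 3, 5 and 6. Cells with both made up at most 0.30% of any library. Libraries 2 and 4 therefore did not come from the same animal as libraries 1, 3, 5 and 6. Whether libraries with the same sex genes share an animal is not known.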
